A study of Homo sapiens with 4 samples.

How the data were processed

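Messenger RNA levels were measured by RNA sequencing in 4 libraries of MCF10A cells, an established, non-tumour human mammary epithelial line. Per the labels, cells were infected with a lentivirus that carried an empty vector, Zeb1, Snail or Ovol2 together with a fluorescent marker. Fluorescent cells were sorted 6 days later, total RNA was extracted on columns, and libraries were made with a TruSeq RNA kit. Each of the 4 groups held 1 library, so no spread between replicates could be measured, and no p-value, standard error or interval for a difference between conditions was computed.

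The authors deposited 3 tables, each of which sets the empty vector library beside 1 factor library. Each table had 25360 rows with 25317 gene symbols. The deposited expression values were taken as FPKM, fragments scaled to transcript length and to library size, because the submitters' processing notes name TopHat, Cufflinks, Cuffdiff and the hg19 build and because the values behaved like FPKM. No column header names the unit, and versions, gene annotation, strand setting and any further scaling between libraries were not given in the sources used here. The empty vector values were the same in all 3 tables, so the tables share a scale and the factor libraries could be set against each other.

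Per the file headers, each deposited table also holds the authors' own comparison, with a p-value, a Benjamini-Hochberg adjusted p-value and a signed fold. The deposited number of values was 1 per side in every row and the degrees of freedom were 8, so these deposited p-values describe a model of 1 library against 1 library and do not measure the spread between cultures. In the authors' deposited tables the adjusted p-value lay below 0.05 in 19748 rows for Zeb1 (77.9%), 20539 rows for Snail (81.0%) and 21893 rows for Ovol2 (86.3%). They were not used to name genes. Counts from them are given only as an alternative.

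The 43 rows that repeat a symbol were summed with their namesakes. The measure of each gene was the log2 of the ratio of FPKM + 1 in the factor library to FPKM + 1 in the empty vector library. The pseudocount of 1 FPKM understates the difference of genes with low values. Genes with at least 1 FPKM in either library of a comparison were kept. In place of a test, a gene was called higher or lower when it differed by 2-fold or more on that scale, a log2 ratio of 1 or more in size. Fold values without a log2 are plain ratios of FPKM, and none was given against a gene listed at 0.

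Gene lists were fixed before the data were examined. The 26 lists were EMT and MET transcription factors, epithelial adhesion and tight junctions, epithelial polarity, trafficking and splicing regulators, desmosomes and hemidesmosomes, basal keratins and basal markers, luminal markers, squamous differentiation, mesenchymal markers, collagens and collagen crosslinking, proteases and their inhibitors, TGF-beta ligands, receptors and targets, WNT signalling, mammary stem and progenitor markers, EGF family ligands and MAPK feedback, cell cycle, p53 targets and cyclin-dependent kinase inhibitors, interferon response, inflammatory cytokines and chemokines, hypoxia and glycolysis, unfolded protein and amino acid stress, cholesterol synthesis, mitochondrially encoded transcripts, ribosomal proteins, and immune cell, endothelial, and neural and muscle markers. For each list the median log2 ratio of its kept members was ranked among the medians of 10000 random lists of the same size, matched in 20 bins of mean expression. A median below the 2.5 or above the 97.5 percentile was said to stand apart. This describes these libraries and is not a test of the conditions. Of 66 medians over 22 lists, 37 stood apart, against 3.3 that a 5% rate would give. All comparisons share the empty vector library, and genes of a list may vary together between cultures. The excess therefore does not measure effects of the factors.

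The named genes followed a rule also fixed before the data were examined. It took the 3 delivered factors in every library, the 10 highest and 10 lowest log2 ratios per comparison among genes at 5 FPKM or more in either library, up to 4 members with the largest log2 ratio of each list described, CDH1, CDH2, VIM, FN1, EPCAM and ESRP1 in every comparison, and the 5 leading genes each way that were shared by Zeb1 and Snail or opposed between Ovol2 and either of them. Whether the delivered coding sequences were human is not given in the sources used here, so the values of ZEB1, SNAI1 and OVOL2 may not count all delivered transcripts. Where a count of 5 or fewer is given, and for the lower basal markers with Ovol2, further genes were named after their values had been seen.

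Overlaps between comparisons were set beside the overlap of independent lists and beside a simulation of unchanged libraries that share the empty vector library, drawn 20 times with a noise of 20% (coefficient of variation), an assumed value. The steps were tested on simulated data with the same noise of 20% but without counting error. The simulation of unchanged libraries also drew counting error at the estimated depths. In the test of the steps, both sides were drawn from the empty vector library, with a separate random draw per comparison and no factor library. Differences were planted only in genes at 5 FPKM or more in the empty vector library. Genes given a 4-fold or 8-fold difference passed the 2-fold rule in 96.0% to 100.0% of cases. Of unchanged genes, 0.521%, 0.503% and 0.44% passed it in the separate draws. These values are not rates of false calls for the Zeb1, Snail and Ovol2 libraries. A planted list ranked at percentile 100.0 in each draw, and 4 of 60 lists with no planted difference stood apart in each.

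Counts of fragments were not used here. The lowest values of a library lay in steps, and the ratio of these steps between libraries gave a relative depth of 1.18 (Zeb1), 1.08 (Snail) and 0.829 (Ovol2) of the empty vector library. With transcript lengths of GENCODE 29 this came to about 29000000 fragments for the empty vector, 34100000 for Zeb1, 32000000 for Snail and 24600000 for Ovol2, an approximation because the authors' gene models were not used. Both estimates assume that values were scaled only by the number of fragments of their own library, which the sources used here do not state. The GENCODE 29 annotation belongs to GRCh38 and the deposited values to hg19, so it served only for lengths and gene types and no coordinates are given.

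Alternatives fixed beforehand were pseudocounts of 0.1 and 5 FPKM, no filter, a filter of 5 FPKM, ratios centred on the median of genes at 5 FPKM or more in both libraries, upper quartile scaling, the highest row per symbol, and the authors' deposited calls. Ratios corrected for the median per transcript length (20 bins), protein-coding genes alone, and upper quartile scaling for lists and named genes were added after the data had been seen. Genes of near-identical families (SPRR1A and SPRR1B, S100A7, SERPINB3, AKR1B10, KRT6A, KRT6B, KRT6C, KRT14, KRT16 and KRT17) may share reads with their copies, so their values are uncertain, and so are the values of small nucleolar RNAs, which lie within other genes. Without a known strand setting, genes that overlap on opposite strands could not be told apart. The mitochondrially encoded list had 0 members among the symbols of the tables and gave no result. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.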

Results

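Gene expression was compared in MCF10A mammary epithelial cells 6 days after delivery of an empty vector, of Zeb1 or Snail, transcription factors that drive the epithelial-to-mesenchymal transition (EMT), or of Ovol2, a transcription factor that drives the opposite transition (MET). There was 1 library per group and 4 in all. The differences below therefore have no replicate check and describe these libraries. Depth, estimated from the steps between the lowest values, was about 29000000 fragments for the empty vector, 34100000 for Zeb1, 32000000 for Snail and 24600000 for Ovol2. At least 1 FPKM was reached by 11359 genes in the empty vector library, 11310 in the Zeb1, 11258 in the Snail and 10118 in the Ovol2 library. RMRP and RPPH1, the RNA parts of RNases MRP and P, together held 24.6% of all FPKM in the empty vector library, 22.1% in the Zeb1, 18.7% in the Snail and 40.6% in the Ovol2 library.

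Each delivered factor was highest in its own library. ZEB1 was at 0.260 FPKM in the empty vector library and 17.3 in the Zeb1 library, with 0.536 in the Snail and 0.0380 in the Ovol2 library. SNAI1, which encodes Snail, was at 99.7 FPKM in the Snail library and at 0.152, 0.436 and 0.725 in the empty vector, Zeb1 and Ovol2 libraries. OVOL2 was already expressed in the empty vector library at 6.32 FPKM and stood at 78.3 in the Ovol2, 5.26 in the Snail and 0.563 in the Zeb1 library. The epithelial cadherin CDH1 was at 60.4, 9.99, 46.0 and 30.8 FPKM in the empty vector, Zeb1, Snail and Ovol2 libraries. Vimentin (VIM), an intermediate filament of mesenchymal cells, was at 12.6, 181, 95.6 and 1.05 FPKM in the same order.

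**Figure D1:**
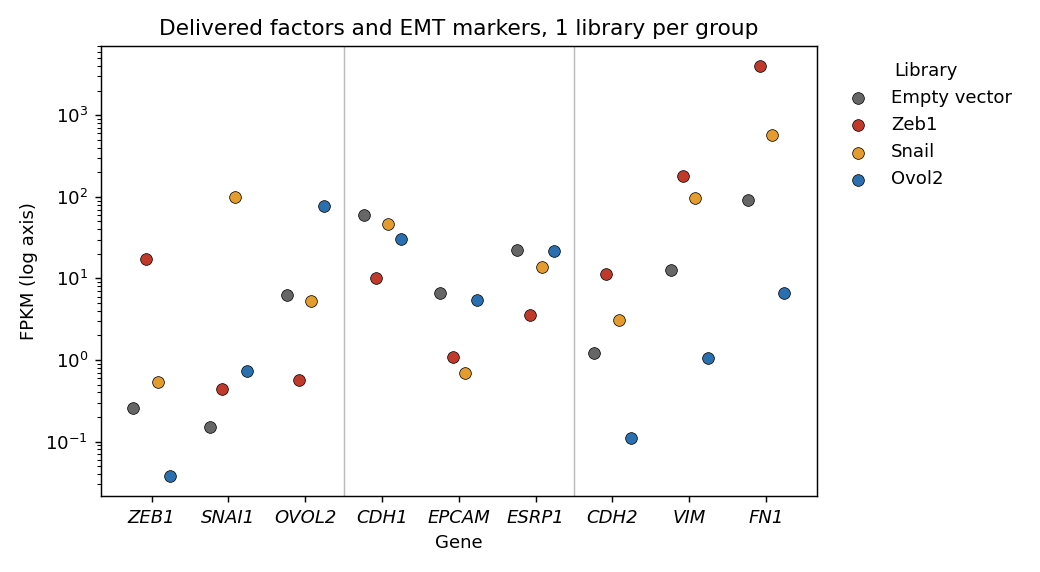
FPKM (log axis) of the 3 delivered factors, 3 epithelial genes and 3 mesenchymal genes, with 1 point per library. Each factor is highest in its own library, and FN1 spans from 6.60 FPKM in the Ovol2 library to 3982 FPKM in the Zeb1 library.

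Zeb1 against the empty vector addressed which genes an EMT factor turns up or down. In the Zeb1 library the genes of the extracellular matrix were far higher. Fibronectin (FN1) stood at 3982 FPKM against 92.7 (log2 ratio 5.41), the proteoglycan decorin (DCN) at 604 against 11.1 (5.64), periostin (POSTN) at 510 against 14.9 (5.01), and the fibrillar collagen COL3A1 at 59.5 against 0.0700 (5.82). The proteoglycan LUM, the microfibril protein FBN1, the growth factor binding protein IGFBP3, the metalloproteinases ADAMTS1 and PAPPA and the secreted ligand WNT5A completed the 10 highest, with log2 ratios of 5.36, 5.22, 5.26, 5.05, 4.53 and 4.79. At the other end, the calcium-binding S100A14 was at 36.8 against 409 FPKM (-3.44), the basal keratin KRT15 at 11.2 against 125 (-3.36) and the ion transport regulator FXYD3 at 11.9 against 119 (-3.22). The others of the 10 lowest were SNORD15A, TNS4, TNNI2, SYT8, LAD1, CBLC and TINAGL1, with log2 ratios between -2.93 and -2.80.

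Of the mesenchymal markers, 17 of 22 kept members were higher by 2-fold or more and 0 lower, with a median log2 ratio of 2.53 that lay at percentile 100 of random lists. DCN, FN1, LUM and FBN1 led this list, VIM stood at 3.75, and the neural cadherin CDH2 was at 11.3 against 1.23 FPKM (2.47). Of the collagens and their crosslinking enzymes, 11 of 15 were higher and 1, COL16A1 (-1.69), lower (median 1.25). The higher ones included COL8A1 (3.67), COL1A1 (2.54) and the lysyl hydroxylase PLOD2 (1.79). The TGF-beta list had 7 higher and 1 lower of 22 (median 0.60, apart), led by the ligand subunit INHBA (2.30), the pseudoreceptor BAMBI (2.22) and CTGF (2.07), with ID1 lower (-1.87).

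The epithelial lists lay on the other side. Of the polarity, trafficking and splicing regulators, 19 of 22 were lower and 0 higher (median -1.96), led by the small GTPase RAB25 (-2.74), the adaptor subunit AP1M2 (-2.64), MAL2 (-2.56) and the splicing regulator ESRP1 (-2.37). Adhesion and tight junction genes had 11 of 18 lower and 0 higher (median -1.32), with CDH1 at -2.48, CLDN1 at -1.97, MARVELD3 at -1.95 and EPCAM at -1.87. Desmosomes and hemidesmosomes had 12 of 19 lower (median -1.28), led by COL17A1 (-2.36) and PKP3 (-2.19). Basal keratins and basal markers had 14 of 15 lower (median -2.24), with SFN at -2.79, S100A2 at -2.68 and FAT2 at -2.32 behind KRT15. The squamous list had 7 of 12 lower (median -1.17), led by the alarmin S100A9 (-2.49). Each of these 5 medians stood apart.

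Among the factors themselves, the EMT and MET transcription factor list did not stand apart (median -0.21, percentile 25.1), since its members went both ways. Apart from ZEB1 (3.86), the largest ratios belonged to the epithelial regulators GRHL2 (-2.25), OVOL2 (-2.23) and ELF3 (-2.22). The cell cycle list had 13 of 30 members lower and 0 higher (median -0.95, percentile 0), led by the replication helicase subunits MCM2 (-1.64) and MCM5 (-1.39), and the cholesterol synthesis list had 11 of 20 lower (median -1.04), led by DHCR7 (-1.75), MVK (-1.53) and SQLE (-1.45). Ribosomal protein genes had 6 of 30 lower (median -0.82, percentile 0.77) and RPS3 the lowest ratio (-1.23). With a filter of 5 FPKM this last list no longer stood apart. Centring left 7 of 30 cell cycle and 2 of 30 ribosomal genes lower, and correction for transcript length 7 and 1.

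In all, 539 of 11922 kept genes were higher by 2-fold or more in the Zeb1 library and 1012 lower, so that 34.8% of them were higher. Centring the ratios on the median of well expressed genes, which moved the median by 0.12, gave 712 higher and 769 lower, 48.1% of them higher.

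**Figure D2:**
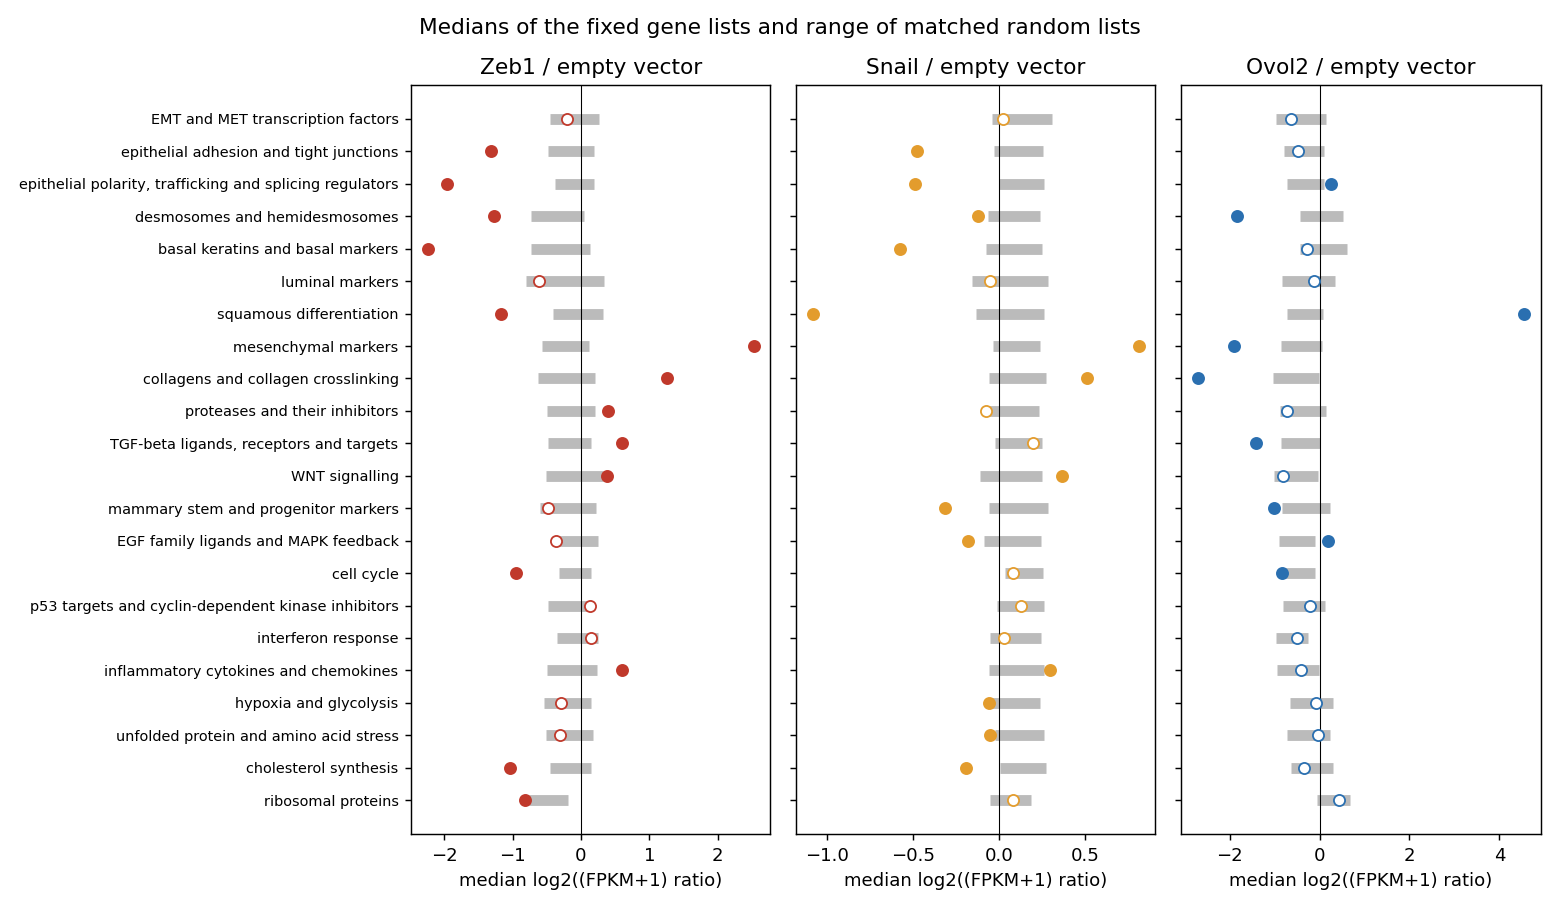
Median log2((FPKM+1) ratio) of each fixed gene list (points) in the Zeb1, Snail and Ovol2 libraries against the empty vector, with a separate x axis per panel. Grey bars span the central 95% of 10000 matched random lists, and filled points lie outside them: mesenchymal markers are at 2.53, 0.81 and -1.91 and squamous differentiation at -1.17, -1.08 and 4.55.

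Snail against the empty vector addressed the same question for the second EMT factor. The Snail library was closer to the empty vector. After SNAI1 (6.45) came DCN at 131 against 11.1 FPKM (3.45), POSTN at 154 against 14.9 (3.28), VIM at 95.6 against 12.6 (2.83), FBN1 (2.81) and FN1 at 576 against 92.7 (2.62). The WNT antagonist DKK1 was at 526 against 89.6 FPKM (2.54), and WNT5A (2.40), the sphingosine phosphate receptor S1PR3 (2.34) and IGFBP3 (2.29) completed the 10 highest. The lowest were KRT15 at 11.1 against 125 FPKM (-3.37), the tetraspanin TSPAN1 (-2.80), the protease inhibitor SERPINB13 (-2.64), the receptor TREM2 (-2.60), the small nucleolar RNAs SNORA47 (-2.33) and SNORA80B (-2.30), the cornified envelope gene SPRR1B (-2.28), the water and glycerol channel AQP3 (-2.28), the adhesion molecule EPCAM at 0.683 against 6.61 FPKM (-2.18) and TMC4 (-2.10).

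Mesenchymal markers had 9 of 20 members higher and 0 lower (median 0.81, percentile 100), and collagens 3 of 14 higher and 0 lower (median 0.51), namely COL3A1 (1.62), the lysyl oxidase LOX (1.61) and COL4A1 (1.08). The squamous list had 7 of 13 lower (median -1.08), with KLK5 at -1.98, S100A8 at -1.73 and S100A9 at -1.66. The polarity list had 6 of 22 lower (median -0.49), led by the membrane protease ST14 (-2.08), MAL2 (-1.69), CRB3 (-1.27) and RAB25 (-1.25), and the adhesion list 4 of 18 lower (median -0.48), namely EPCAM, CLDN7 (-1.42), CXADR (-1.25) and CLDN4 (-1.24). CDH1 itself was at 46.0 against 60.4 FPKM (-0.38), ESRP1 at -0.66 and CDH2 at 0.88, none of them past the 2-fold rule. For CDH2, at 3.11 against 1.23 FPKM, this was due to the pseudocount, as the plain ratio was 2.53. Basal markers had 3 of 15 lower (median -0.58), namely KRT15, FAT2 (-1.64) and KRT6B (-1.26). Desmosomes had 0 of 19 past 2-fold (median -0.12, percentile 0.35, apart), with JUP at -0.65.

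The TGF-beta list (median 0.19, percentile 86.3), the cell cycle list (0.08, percentile 11.8) and the ribosomal proteins (0.08, percentile 49.9) did not stand apart in the Snail library, and the cholesterol list did with a small median (-0.19) and 0 of 20 members past 2-fold. The EMT and MET transcription factors did not stand apart either (median 0.02, percentile 9.38), with ELF3 at -1.78, ZEB2 at 0.93 and EHF at -0.78 after SNAI1 itself. In all, 117 of 11644 genes were higher and 175 lower, and 40.1% of them were higher. Centring, which moved the median by -0.14, gave 78 higher and 251 lower, and protein-coding genes alone gave 106 higher and 99 lower. In the simulated unchanged libraries, with assumed noise and counting error, an average of 59.95 genes were higher and 57.85 lower in the Snail comparison.

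Ovol2 against the empty vector addressed what a factor of the opposite transition does in cells that are already epithelial. Genes of squamous differentiation, the programme by which epidermal cells build the cornified layer, were much higher. KRTDAP stood at 2391 against 0.677 FPKM (10.48), S100A7 at 3214 against 1.80 (10.17), the calcium-binding S100P at 4002 against 8.39 (8.74) and S100A9 at 4144 against 16.5 (7.89). SPRR1A was at 317 against 0.0790 FPKM (8.20), the protease inhibitor elafin (PI3) at 253 against 0.118 (7.83), the skin protease KLK7 at 351 against 0.844 (7.58) and SERPINB3 at 234 against 0.613 (7.18). AKR1B10, an aldo-keto reductase, was at 497 against 0.848 FPKM (8.07), and SPRR3 reached 254 FPKM while it was listed at 0 in the empty vector library. Among the 10 lowest genes, the laminin chain LAMA3 was at 3.53 against 98.5 FPKM (-4.46), the anchoring fibril collagen COL7A1 at 1.83 against 50.7 (-4.19) and the crosslinking enzyme LOX at 1.51 against 33.2 (-3.77). COL12A1, COL4A2, LAMB1, PXDN, FSTL1, HEG1 and the receptor tyrosine kinase ROS1 had log2 ratios between -4.09 and -3.78.

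Of the squamous list, 26 of 27 kept members were higher by 2-fold or more and 0 lower (median 4.55, percentile 100), with CDSN as the exception at 2.02 against 0.786 FPKM (0.76). Most of these members passed the filter of 1 FPKM only through the Ovol2 library, so they could not have been called lower. Members at 1 FPKM or more in the empty vector library were all higher by 2-fold or more. The genes of this list were low in the other libraries, where the highest member was S100A9 at 16.5 FPKM in the empty vector and KRT10 at 14.9 in the Zeb1 and 18.7 in the Snail library. The polarity, trafficking and splicing list stood apart on the higher side (median 0.24, percentile 99.8) with 4 of 24 higher and 4 lower, and TMEM125 (11.2 against 0.0770 FPKM), BSPRY (3.19), CRB3 (1.95) and RAB25 (1.56) were the 4 higher. The 4 lower were CDS1 (-1.34), SCNN1A (-1.16), PARD3 (-1.15) and INADL (-1.13). Adhesion and tight junctions did not stand apart (median -0.47, percentile 30.9). CLDN4 (3.61), PVRL4 (2.47), TJP3 (2.21), CLDN8 (1.26) and CLDN7 (1.07) were higher there and TJP1 (-1.83) and CLDN1 (-1.77) lower, while CDH1 was at 30.8 against 60.4 FPKM (-0.95), EPCAM at -0.22 and ESRP1 at -0.05.

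**Figure D3:**
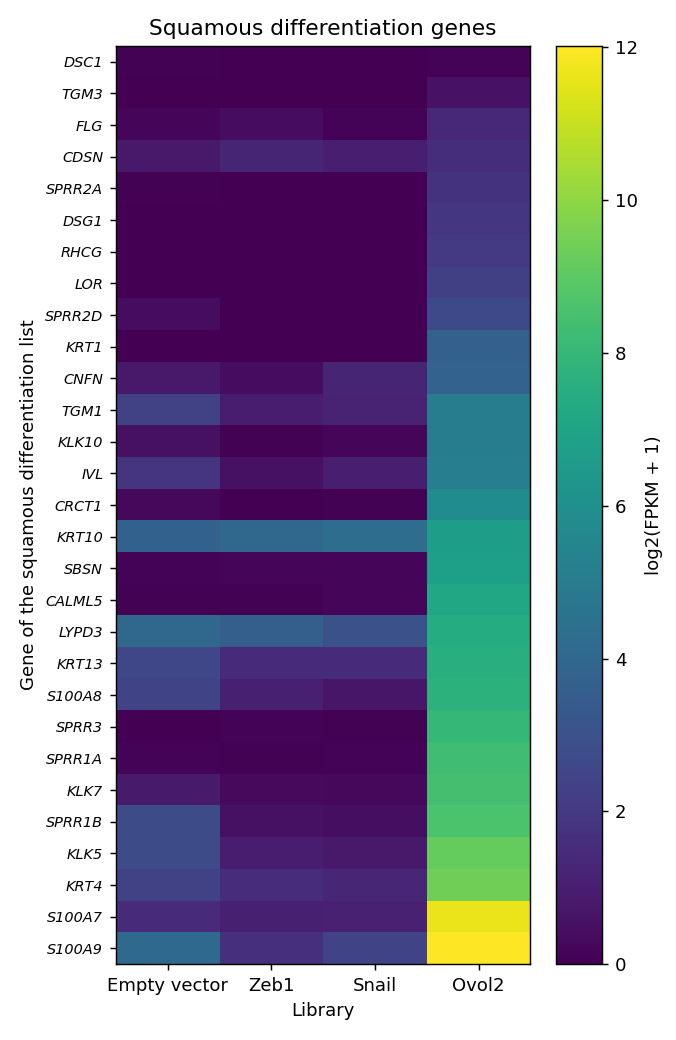
Log2(FPKM + 1) of the 29 genes of the squamous differentiation list (rows) in the 4 libraries (columns), sorted by their value in the Ovol2 library. S100A9 and S100A7 reach 4144 and 3214 FPKM in the Ovol2 library, and the highest value of any member in the other libraries is 18.7 FPKM.

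Mesenchymal markers had 14 of 18 members lower and 1 higher (median -1.91, percentile 0), led downward by FSTL1 (-3.79), FN1 (-3.62) and the protease FAP (-3.25), with VIM at -2.73 and CDH2 at -1.01. The exception was S100A4 at 505 against 34.0 FPKM (3.85). Collagens and their crosslinking enzymes had 12 of 13 lower (median -2.71), and the TGF-beta list 13 of 21 lower and 1, ID1 (1.08), higher (median -1.41), with the receptor TGFBR1 at -3.51, PMEPA1 at -3.19, CTGF at -2.97 and LTBP2 at -2.93. Desmosomes and hemidesmosomes had 13 of 19 lower (median -1.84), among them LAMA3, COL17A1 (-3.04), DST (-2.94) and the integrin ITGB4 (-2.87), which join basal cells to the matrix, and 1 higher, PERP (1.45). Basal keratins and basal markers went both ways, 5 higher and 7 lower of 16 (median -0.27, percentile 8.57). The higher ones were KRT16 at 965 against 41.4 FPKM (4.51), KRT6B (3.40), KRT15 (2.16), KRT6C (2.10) and SFN (1.29). The lower ones were KRT5 at 215 against 2929 FPKM (-3.76), EGFR (-2.98), KRT14 (-1.72), CAV1 (-1.70), CDH3 (-1.55), FAT2 (-1.49) and TP63 (-1.43). The transcription factors GRHL1 (3.20), ELF3 (2.39) and GRHL3 (2.20) were higher with OVOL2 (3.44), while TWIST1 (-2.00), TCF4 (-1.32) and TWIST2 (-1.07) were lower. Their list as a whole, with 4 higher and 3 lower of 13, did not stand apart (median -0.64, percentile 21.9).

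The cell cycle list was lower in the Ovol2 library (median -0.84, percentile 1.46) with 12 of 30 members lower, led by CENPF (-3.02), TOP2A (-2.48), MKI67 (-1.92) and KIF20A (-1.76). With a filter of 5 FPKM this list no longer stood apart (-0.87), and correction for transcript length left 3 of 30 members lower. Cholesterol synthesis (median -0.34, percentile 23.5) and ribosomal proteins (0.43, percentile 69.0) did not stand apart. In all, 806 of 11812 genes were higher and 2965 lower, 21.4% of them higher, and the median of all kept genes was -0.51. Upper quartile scaling gave 1702 higher and 1453 lower, and centring 1053 higher and 2158 lower, 32.8% of them higher. The ratios also followed transcript length (Spearman's rho -0.314 across genes, which are not independent replicates), from a median of -0.30 in the shortest 10% to -1.03 in the longest 10%. The trend had the opposite sign in the Zeb1 (rho 0.194, from -0.33 to 0.16) and Snail (rho 0.189) libraries. After correction for length the medians were 5.10 for the squamous, -2.24 for the collagen, -1.43 for the mesenchymal, -0.71 for the TGF-beta, -1.06 for the desmosome and -0.37 for the cell cycle list, each still apart. The polarity list came to 0.80 (apart), with 9 higher and 0 lower, and the adhesion list to 0.03 (not apart).

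The 3 comparisons share the empty vector library, and their overlaps were counted over 12388 genes. The simulated libraries hold no changed genes, so their lists are shorter than the observed ones. Simulated overlaps show what the shared control gives without any effect and are no baseline for lists of the observed sizes. Zeb1 and Snail had 93 genes higher in both, where independent lists of these sizes give 5.09 and simulated unchanged libraries 9.30, and 131 lower in both, where these values are 14.3 and 9.35. Against this, 2 genes were higher with Zeb1 and lower with Snail, the secreted chaperone CLU (1.06 and -1.58) and the sorting receptor SORT1 (1.23 and -1.16), and 0 the other way. DCN, POSTN, VIM, FBN1 and FN1 led the genes higher in both, and KRT15, TSPAN1, TREM2, SNORA80B and AQP3 those lower in both. Across genes the log2 ratios correlated with r = 0.624 (rho 0.593), against 0.505 for simulated unchanged libraries, and their covariance was 0.168 against 0.0660. The single control library could not be split, so part of the excess may come from it.

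Ovol2 had both opposed and shared genes with each of them. Simulated counts of opposed genes are low by construction, since the shared control moves both ratios alike, and are no baseline for these lists. There were 206 genes lower with Ovol2 and higher with Zeb1 (129 for independent lists, 0.1 simulated), led by FN1, POSTN, VIM, FSTL1 and COL8A1, and 143 higher with Ovol2 and lower with Zeb1 (65.8 and 0.150), led by FXYD3, FGFBP1, S100A9, CRABP2 and AQP3. Against this, 210 genes were lower with both Ovol2 and Zeb1 (242 and 9) and 16 higher with both (35.1 and 9.55). AQP3 was at 661 FPKM in the Ovol2, 39.3 in the empty vector, 7.33 in the Snail and 6.58 in the Zeb1 library. Against Snail, 59 genes were lower with Ovol2 and higher with Snail (28.0 and 0.1), led by POSTN, VIM, FN1, ITGA1 and GAS1, and 51 higher with Ovol2 and lower with Snail (11.4 and 0.05), led by SERPINB13, SPRR1B, AQP3, KRT15 and ALDH3A1. Centring gave 30 and 77 for these 2 counts, so their order depended on scaling. A further 45 genes were lower with both Ovol2 and Snail (41.9 and 9.50) and 2, WNT5A and CDKN1C, higher with both (7.61 and 10.6). The correlation across genes was -0.19 with Zeb1 (rho -0.218) and -0.306 with Snail (rho -0.341), where simulated unchanged libraries gave 0.497 and 0.498 because of the shared control. The covariances were -0.136 and -0.115, against 0.0660 and 0.0670. The length trends of Ovol2 and of the other factors run opposite, and among genes kept in both comparisons the length correction took the correlation from -0.258 to -0.226 with Zeb1 and from -0.337 to -0.316 with Snail. It left 139 and 153 opposed genes with Zeb1 and 26 and 75 with Snail, in the order given above.

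**Figure D4:**
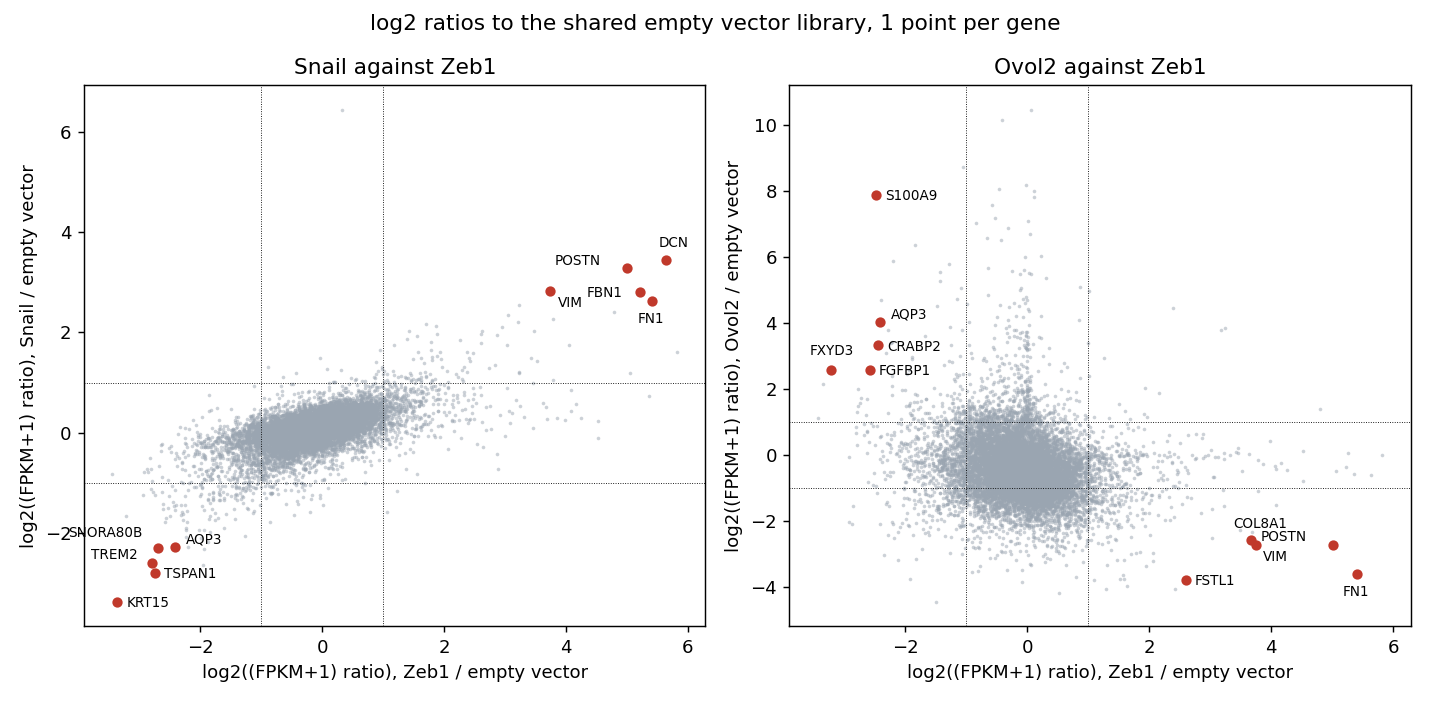
Log2((FPKM+1) ratio) to the empty vector for each of 12388 genes, Snail against Zeb1 on the left and Ovol2 against Zeb1 on the right, with dotted lines at the 2-fold rule and the 5 leading shared or opposed genes each way in red. VIM lies at 3.75 for Zeb1, 2.83 for Snail and -2.73 for Ovol2.

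Set directly against the Snail library, the Zeb1 library had 275 genes higher and 754 lower by 2-fold or more. Mesenchymal markers were higher with Zeb1 (12 of 21, median 1.46), while polarity regulators (14 of 21 lower, median -1.16), basal markers (10 of 15 lower, median -1.53) and the cell cycle list (13 of 30 lower, median -0.96) were lower. The squamous list had 0 of 11 members apart by 2-fold (median -0.04). Centring turned the counts to 514 higher and 348 lower. The Ovol2 library had 1731 genes higher and 3448 lower than the Zeb1 library, and 1046 higher and 3833 lower than the Snail library. Collagens were lower in 14 of 15 members against Zeb1 (median -4.71) and 13 of 14 against Snail (-3.25). Polarity regulators were higher in 18 of 24 and lower in 0 against Zeb1 (2.32), and higher in 10 of 24 and lower in 3 against Snail (0.84).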

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

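Protein-coding genes alone and the correction for transcript length were chosen after seeing the data, as was upper quartile scaling for lists and named genes. The highest row per symbol left each count within 1.5 times, and so did removing the filter, by construction, since genes below 1 FPKM in both libraries cannot pass the 2-fold rule. Counts moved most with the authors' adjusted p-value, given below, and several moved by more than 1.5 times with the pseudocount, which sets how far low genes can differ. With 0.1 FPKM, higher and lower genes were 885 and 1541 for Zeb1, 217 and 361 for Snail and 521 and 1205 for Zeb1 against Snail. With 5 FPKM they were 224 and 416 for Zeb1, 37 and 60 for Snail and 437 and 877 for Ovol2. A pseudocount of 0.1 gave overlaps of 213 genes higher and 329 lower in both Zeb1 and Snail, 469 lower with Ovol2 and higher with Zeb1, 304 the other way, 144 lower with Ovol2 and higher with Snail, and 159 the other way. A filter of 5 FPKM gave 109 genes lower with Snail and 181 higher with Zeb1 than with Snail, because fewer genes were counted. Centring gave 514 higher and 348 lower for Zeb1 against Snail, 30 genes lower with Ovol2 and higher with Snail, and 77 the other way. Upper quartile scaling gave 1702 higher and 1453 lower for Ovol2, where it moved the median of all kept genes by 0.43 and centring by 0.17, and the length correction gave 1314 and 1012. That correction left 26 genes lower with Ovol2 and higher with Snail. Protein-coding genes alone left 99 lower with Snail. The authors' adjusted p-value under 0.05 called 10046 rows higher and 9702 lower for Zeb1, 13936 and 6603 for Snail and 9408 and 12485 for Ovol2, since their calls set no minimum size or level. Under the filter of 5 FPKM the medians of the cell cycle list for Ovol2 (-0.87), the ribosomal list for Zeb1 (-0.82) and the hypoxia (-0.03) and unfolded protein (-0.02) lists for Snail no longer stood apart, and the length correction did the same to the hypoxia list for Snail (-0.15). The cause was not tested. The medians of the adhesion, polarity, desmosome, basal, squamous, mesenchymal, collagen and TGF-beta lists kept their standing under these settings in each comparison. With that filter the WNT list had too few members for a median in the Zeb1 comparison. Of 395 list values under 6 settings, 378 kept their standing, 5 lost it, 12 gained it and 0 turned. The gains were the EGF list for Zeb1 (0.1 FPKM pseudocount, 5 FPKM filter, length correction), the stem list for Zeb1 (5 FPKM filter, length correction), the interferon list for Zeb1 (0.35, length correction), the protease list for Snail (upper quartile scaling) and Ovol2 (0.1 FPKM pseudocount, length correction), the WNT and cytokine lists for Ovol2 (5 FPKM filter) and the unfolded protein list for Ovol2 (0.63, length correction). Of 404 values of named genes, 398 stayed on their side of the 2-fold rule. CDH2 in the Ovol2 library fell inside it when centred (-0.84) or scaled to the upper quartile (-0.94). A further 4 values passed the rule only with a pseudocount of 0.1 FPKM. Scaling turned the sign of 11 small list medians, none of which stood apart. Genes with a given status in the authors' tables were not counted apart, and that alternative was not run, as no such column was used here. Leaving out a replicate was not possible with 1 library per group. Depth of about 24600000 to 34100000 fragments limits genes near 0, where 1 fragment more or less changes a value from 0.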

Other observations

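In the Zeb1 library the inflammatory cytokine list stood apart on the higher side (6 of 16 higher, 2 lower, median 0.59), with the neutrophil chemokines CXCL1 at 168 against 9.05 FPKM and CXCL8 at 66.8 against 3.29, CXCL3 at 3.07 on the log2 scale and IL1A at -1.43. The same list had a median of 0.29 in the Snail library (apart), with SAA1 the 1 member past 2-fold (-1.17), and -0.41 in the Ovol2 library (not apart, 3 higher and 7 lower), where the iron-binding protein LCN2 was at 50.1 against 0.488 FPKM. HBEGF, an epidermal growth factor family ligand, was at 5.47 FPKM in the empty vector, 0.384 in the Zeb1, 0.678 in the Snail and 26.3 in the Ovol2 library, and its list had medians of -0.37 (not apart), -0.18 and 0.18 (both apart). In the Zeb1 library this list and the stem list stood apart with a filter of 5 FPKM (-0.86 and -0.78). The WNT list had medians of 0.38 and 0.37 (both apart) in the Zeb1 and Snail libraries and -0.80 (not apart) in the Ovol2 library. WNT5A was higher in all of them (4.79, 2.40 and 1.39), while WNT4 was at 2.45 FPKM in the empty vector, 0.383 in the Zeb1, 0.435 in the Snail and 11.3 in the Ovol2 library. Among proteases and inhibitors, SERPINE2 (4.08), PLAT (2.77) and MMP2 (2.36) were higher in the Zeb1 library, where the list stood apart (8 of 20 higher, 5 lower, median 0.40). That list did not stand apart with Snail (-0.08), where MMP3 (-1.52) and PLAU (-1.44) were lower, or with Ovol2 (-0.73).

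The luminal list did not stand apart in any of the 3 comparisons (medians -0.61, -0.05 and -0.11), but AGR2, a secretory pathway protein, was at 25.1 FPKM in the Ovol2 library against 0.140 in the empty vector, and MUC1 at 0.353 against 4.95. The stem and progenitor list had medians of -0.49 (not apart), -0.31 and -1.005 (both apart), with the aldehyde dehydrogenase ALDH1A1 at 46.7 against 0.483 FPKM in the Ovol2 library and MET (-3.38) and ITGB1 (-2.36) lower there. The p53 and cell cycle inhibitor list did not stand apart (0.13, 0.13 and -0.21), with GDF15 at 71.0 against 3.20 FPKM in the Ovol2 library. The interferon list did not stand apart either (0.15, 0.03 and -0.51), except for Zeb1 after length correction (0.35). The glucose transporter SLC2A1 was at 32.9 FPKM in the empty vector, 11.7 in the Snail and 163 in the Ovol2 library, in a hypoxia and glycolysis list with medians of -0.28, -0.06 (apart, but not with a filter of 5 FPKM or after length correction) and -0.08. The unfolded protein and amino acid stress list had medians of -0.31, -0.05 (apart, but not with a filter of 5 FPKM) and -0.03. Few markers of other cell types were kept. The highest immune marker was CD14 at 17.0 FPKM in the Zeb1 library against 1.46 in the empty vector (2.87), with CD68 at 1.09 on the log2 scale, the highest endothelial marker ENG at 1.40 to 2.94 FPKM in the factor libraries, and the highest neural or muscle marker TUBB3 at 45.1 FPKM in the Ovol2 library. MAP2 was at 19.7 FPKM in the Zeb1 and 10.4 in the Snail library against 1.66 in the empty vector. These lists had 3, 1 to 2 and 2 kept members.

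Of the tests that follow, those of depth and of a fixed share of Zeb1-like cells were chosen after the results had been seen, as were the comparisons with upper quartile scaling, with genes centred on their own median, and of the Snail genes with simulated libraries. The correction for transcript length was likewise added after the data had been seen.

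In the Ovol2 library squamous genes were higher, collagens were lower and more genes were lower than higher (2965 against 806), with lower ratios for longer transcripts. The length trend does not account for the lists: after its removal the squamous median was 5.10, above the random range that ends at 0.471, and the collagen median -2.24, below the range that starts at -0.52. For the excess of lower genes, the length correction left 0.77 genes lower per gene higher, but centring the same genes on their own median left 0.62, so that test cannot separate length from scaling. Centring on well expressed genes left 2.05 lower per gene higher, just over the bound of 2 set beforehand, and upper quartile scaling left 0.85, so scaling and a broad effect of Ovol2 cannot be told apart without replicates or spiked-in RNA. Taken as a change of scale, the larger share of RMRP and RPPH1 would move all other genes alike. That share is one of summed FPKM and not of fragments. Without RMRP and RPPH1, FPKM summed to 329894 in the Ovol2 and 282226 in the empty vector library, so the other genes were not lower in sum. After centring, the squamous median was 4.72 and the collagen median -2.54. Upper quartile scaling gave 5.09 and -2.47. Centring and upper quartile scaling moved the median of all kept genes by only 0.17 and 0.43, too little to undo either list. The lists lay on opposite sides, which argues against one change of scale as the source of both. RNA quality, RNA from other cells and what lies behind that larger share were not tested. An effect of Ovol2 on squamous genes and collagens stays a hypothesis.

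Many genes that differed in the Snail library differed by more in the Zeb1 library, 79 of 117 higher and 106 of 175 lower ones (67.5% and 60.6%). Simulated unchanged libraries that share the control gave 6.59% and 7.87%. They hold no effect of either factor, so these values are no baseline for real effects of equal size. The other genes did not differ by more with Zeb1, and the squamous list had about the same median in both (-1.08 and -1.17). A candidate explanation is that a fixed share of the sorted Snail cells had reached the Zeb1-like state. Each gene 4-fold or more apart with Zeb1 would then give the same share, apart from noise. Across 223 such genes the implied share ran from 8.74% at the 25th percentile to 55.2% at the 75th, 6.32 times as much. This ratio was 6.05 among the genes higher with Zeb1 and 2.70 among those lower. Noise of single libraries, for which no allowance was made, widens such ratios, so they alone cannot decide. The same percentiles were 4.37% and 26.4% for the higher genes (median 12.3%) and 28.1% and 75.9% for the lower ones (49.9%). These ranges do not overlap, which argues against one fixed share for both directions. The share was 12.4% for FN1, 3.7% for COL3A1, 49.2% for VIM and 28.4% for CDH1, while EPCAM (107%) and KRT15 (100.1%) were as low with Snail as with Zeb1. Gene-specific responses to the 2 factors, or stages that genes pass at different times, stay open and were not tested.

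Fewer genes were listed at 0 in the Snail (3340) and Ovol2 (3478) libraries than in the empty vector (6482) and Zeb1 (5228) libraries. Depth as estimated here argues the other way for Ovol2, whose relative depth was 0.829. By the same estimate the Zeb1 library was deeper than the Snail library (1.18 against 1.08) with more genes at 0. Any further scaling between libraries, which was not given, would shift these estimates. Olfactory receptor genes, which mammary cells are not known to use, were above 0 in 10.9% of 367 cases in the empty vector library. The share was 17.2% in the Zeb1, 48.2% in the Snail and 45.5% in the Ovol2 library. In the Snail and Ovol2 libraries this was at least 4.18 times as often as in the empty vector. In the same order, 93 hair keratin-associated protein genes (3.23%, 10.8%, 30.1% and 40.9%) and 13 interferon alpha genes (7.69%, 7.69%, 38.5% and 23.1%) followed. The 27 taste receptor genes did not (66.7%, 66.7%, 74.1% and 63.0%), and 53 protocadherin genes were mostly above 0 in every library (83.0%, 83.0%, 90.6% and 96.2%). The 25 beta-defensin genes followed for Ovol2 more than for Snail (24%, 20%, 28% and 40%). Their mean was 4.55 FPKM in the Ovol2 and 0.0567 in the empty vector library, so in the Ovol2 library they cannot be taken as unused. The olfactory receptor values are consistent with background reads spread over unused genes, for which genomic DNA may be a source, at mean levels of 0.0198 and 0.0226 FPKM that lie far below the 1 FPKM filter. Such low values bear on the authors' deposited tables: of the 1000 genes or transcripts with the smallest p-values, both values lay under 0.1 FPKM in 971 for Snail and 874 for Ovol2, but in 24 for Zeb1.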
